A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

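The study sequenced RNA from stems and leaves of 2-week-old seedlings of the japonica rice cultivar Lijiangxintuanheigu after 24 h at 11, 13 or 25 °C, with 2 biological replicates per temperature according to the series design, for a total of 6 libraries. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.12. The authors' deposited table gives RPKM values (reads scaled to gene length and library total) for each library. The genome build, annotation, counting program and use of strand are not given in the sources used here, and coordinates are printed as the table gives them. Collection times are not given either.

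The table holds 55800 loci with MSU-type identifiers. Identifiers are written in lower case for 32150 loci and in upper case for 23650, and the upper-case loci have a value of 0 in every replicate 2 library, while 2021 of them have a replicate 1 value. Of these 9 pass the expression filter, so the difference in writing affects few tested genes. Every lower-case locus has a value in some replicate 2 library, so upper case coincides with having no replicate 2 value. The RPKM values of 19428 of the tested loci (99.9%) correspond to whole read numbers within a tolerance of 0.02 once each library total is recovered. Recovered totals were 17.02 and 18.75 M reads at 11 °C, 16.96 and 18.74 M at 13 °C and 15.96 and 18.35 M at 25 °C. With these totals 1 read on a gene of 1 kb equals an RPKM of 0.0533 to 0.0626, and 16490 to 18083 genes per library reached an RPKM of 1.

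Genes with RPKM of at least 1 in at least 2 of the 6 libraries were tested, 19438 loci, and 13465 of them (69.3%) have a description from a best protein match in the table. The values were analysed as log2(RPKM + 1) with limma, all 6 libraries in 1 linear model with a mean-variance trend, no further scaling and 3 contrasts: 11 against 25 °C, 13 against 25 °C and 11 against 13 °C. A gene is called when its Benjamini-Hochberg adjusted p is below 0.05. Fold changes are ratios of mean RPKM and are not given for genes at 0 in a group. With 2 libraries per group, no library could be judged an outlier against its own group.

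The model was tested on simulated data with the study's group sizes and a dispersion of 0.0606. It recovered 90%, 88% and 83% of genes set to change 4-fold in the 3 contrasts and 17%, 10% and 10% of those set to change 2-fold. False calls were 7 of 18604, 8 of 18598 and 5 of 18615 genes. Most genes set to change 2-fold were missed in this simulation, which changed 100 genes per fold size. In the study data far more genes were called, 9719 of 19438 at 11 against 25 °C, which makes the adjusted cutoff less strict. The recovered shares therefore do not measure the power in the study data. Of 100 null gene lists, 5, 4 and 0 had an unadjusted camera p below 0.05. Genes were simulated independently and the null lists drawn at random. This result therefore does not check the p-values of lists whose members vary together.

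Gene lists were fixed before the table was opened: 17 lists by locus (cold and dehydration transcription factors; dehydrins, LEA proteins and osmolyte enzymes; antioxidant enzymes; abscisic acid; photosynthesis; chlorophyll synthesis; chlorophyll breakdown; leaf rolling; circadian clock; heat shock proteins and factors; aquaporins; cellulose synthases; jasmonate; cuticle and wax; root markers; meristem and cell cycle markers; reference genes) and 21 by words in the descriptions (photosystem and light-harvesting; ribosomal proteins; small heat shock proteins and chaperones; AP2/ERF; WRKY; NAC; MYB; zinc finger; peroxidases; glutathione S-transferases; cytochromes P450; expansins; LEA proteins; histones; lipid transfer proteins; tubulins and kinesins; terpene synthases; receptor-like kinases; aquaporin proteins; auxin response; transposable element genes). Of 185 members named by locus, 175 are in the table under lower-case identifiers and 144 passed the filter; RbcS4 is absent, and the others, such as OsMYB103L and REL1, are there only in upper case. Symbols come from the fixed lists and were checked against the descriptions, which among measured members are absent for OsLEA3, ACL1, NAL1, CFL1 and OsJAZ13. The descriptions name a different member of the family for some loci, such as carotenoid cleavage dioxygenase 4 for OsNCED1 and PRR95 for OsPRR59.

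The 34 lists with at least 3 measured members were tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, which does not compare a list with other genes. Lists overlap, and reads of close paralogs (Rubisco small subunit, chlorophyll a/b binding, histone and tubulin genes) may be shared between loci. Counts "adjusted over the list alone" adjust p over the members of a list. The overlap of the low-temperature responses was set against 100 simulated draws in which the contrasts share only the 25 °C libraries.

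Genes are named by a rule. Per contrast, it takes the 8 largest rises and 8 largest falls among called genes that meet further conditions. The conditions are a mean RPKM of at least 5, a specific description and no overlap in RPKM between libraries of the groups compared. The rule also takes up to 4 called members per list with the largest change, otherwise the 2 with the highest mean. All measured leaf rolling genes are named. Of all genes with opposite changes, up to 4 with the largest difference between the low temperatures are named as well.

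Replicate numbers come from the sample titles. Deviations of replicate 1 from replicate 2 correlated between groups (0.71 between 11 and 13 °C, 0.61 between 11 and 25 °C, 0.67 between 13 and 25 °C, across genes; genes are not independent replicates), and the principal component with 9.4% of the variance separated the numbers. Replicate number was therefore tried as a block; the labels do not say what the numbers share, and the printed results come from the model without a block.

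Alternatives planned beforehand were a pseudocount of 0.1, no filter, mean RPKM of at least 5, TMM-type factors computed on the RPKM values, quantile scaling, no trend, only the 4 libraries of a contrast, a replicate block, a 2-fold threshold, each library left out, and the other list tests. Chosen after seeing the data were limma-voom on the recovered reads, leaving out 99 loci of organelle type, and the list tests under other scalings and without each library. Count models planned for a table of read counts were not run because the table holds RPKM.

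R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9 were used. Raw reads, splicing and sequence variants were not analysed here.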

Results

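Shoots of 2-week-old rice seedlings of the cultivar Lijiangxintuanheigu, held for 24 h at 11, 13 or 25 °C, differed at most of the loci tested. Of 19438 loci, 13067 changed in at least 1 of the 3 comparisons (limma, adjusted p, 2 biological replicates per temperature). The first 2 principal components held 57.6% and 30.6% of the variance. Replicates correlated at 0.975 at 11 °C, 0.972 at 13 °C and 0.958 at 25 °C across genes; genes are not independent replicates. Levels below are mean RPKM ± SD with n = 2 per temperature, changes are log2 differences of RPKM + 1 ± standard error, and p-values are adjusted values of limma over all genes of a comparison. Unless a paragraph says otherwise, a gene said to rise or fall kept its call when any single library was left out. Leaving out a library also unbalances the replicate numbers, whose deviations are shared between temperatures. Collection times are not given, so a difference in time of day cannot be told from temperature for any change below.

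Against 25 °C, shoots held 24 h at 11 °C had far less of their most abundant photosynthetic transcript and of most aquaporin transcripts, and more of cold transcription factor and ribosomal protein transcripts. RCA (LOC_Os11g47970, chromosome 11, 28934294 to 28936340), which encodes Rubisco activase, dropped 38.2-fold from 31800 ± 6800 to 832 ± 258 RPKM. OsPIP1;1 (chromosome 2, 27044319 to 27047453), a plasma membrane water channel, fell 43.6-fold from 1650 ± 303 to 37.9 ± 14.2 RPKM. Thiamine thiazole synthase 2 (LOC_Os07g34570, chromosome 7, 20724563 to 20726098), which makes the thiazole part of thiamine in plastids, rose 1810-fold from 1.96 ± 0.344 to 3540 ± 201 RPKM. OsDREB1B, a CBF-type activator of cold-responsive promoters, rose by 4.92 ± 0.27 from 0.171 ± 0.151 to 34.6 ± 6 RPKM. Its level at 25 °C rests on few reads (0.0638 and 0.277 RPKM), so no fold is given.

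Phosphomethylpyrimidine synthase (LOC_Os03g47610, chromosome 3, 26952048 to 26959200), which makes the pyrimidine part of thiamine, rose 518-fold to 173 ± 30.7 RPKM at 11 °C. The 29 kDa ribonucleoprotein B (LOC_Os07g43810), an RNA-binding protein of chloroplasts, rose from 5.93 ± 2.51 to 1200 ± 135 RPKM, a log2 change of 7.48 ± 0.29 (adjusted p = 7.34e-06). The gene matching DAG (LOC_Os08g04450), needed for early chloroplast development in snapdragon, reached 593 ± 7.9 RPKM (7.28 ± 0.26). The sigma factor gene sigC (LOC_Os05g51150), whose product directs the plastid-encoded RNA polymerase, rose 422-fold to 196 ± 56 RPKM. Bifunctional nuclease 1 (LOC_Os01g50622) rose by 7.66 ± 0.24, the cysteine-rich receptor-like kinase gene CRK10 (LOC_Os07g43570) by 6.84 ± 0.29, and the aquaporin gene OsPIP2;7 (chromosome 9, 21310129 to 21311548) by 6.67 ± 0.22, or 119-fold, to 650 ± 54.1 RPKM. Among the genes ranked by the naming rule, the largest log2 fall was that of LOC_Os12g08760 (chromosome 12, 4499736 to 4503990), described as carboxyvinyl-carboxyphosphonate phosphorylmutase. It fell 279-fold from 1250 ± 139 to 4.49 ± 0.782 RPKM (limma, adjusted p = 4.74e-06). The senescence-associated cysteine protease gene SAG39 (LOC_Os03g54130) fell 481-fold from 206 ± 39.6 to 0.428 ± 0.157 RPKM. Lichenase-2 (LOC_Os05g31140), a glucanase of grass cell walls, fell by 5.91 ± 0.47, chaperone dnaJ 11 (LOC_Os06g50230) by 5.9 ± 0.23, and glutaredoxin-C1 (LOC_Os01g27140) by 5.74 ± 0.26.

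Genes of photosynthesis fell as a group at 11 °C. Of 21 measured members of the photosynthesis list, 17 fell, 1 rose and 3 did not pass (18 and 1 adjusted over the list alone). The list median was -1.79, and camera with a preset correlation gave an adjusted p = 1.12e-06 (adjusted p = 0.757 with an estimated correlation). Beside RCA, the light-harvesting genes Lhca4 (-4.95 ± 0.26, from 2390 ± 238 to 77.2 ± 16.8 RPKM) and Lhcb4 (-3.43 ± 0.25, from 580 ± 5.45 to 54 ± 15.2 RPKM) and the chlorophyll a/b binding gene CAB1R (-3.34 ± 0.39) had the largest falls. The wider list of photosystem and light-harvesting proteins, taken from descriptions, had 25 falls, 3 rises and 18 not passed of 46 (27 and 3 adjusted over the list alone, 28 and 10 with a replicate block). Its adjusted p = 9.74e-05 became adjusted p = 0.635 with an estimated correlation. Members that fell include the photosystem I subunit LOC_Os07g05480 (-3.87 ± 0.25) and the photosystem II 22 kDa protein LOC_Os04g59440 (-3.9, adjusted p = 3.76e-05). Organelle-type loci moved with the libraries as well: they held 4.61% and 2.99% of reads at 11 °C, 4.37% and 0.709% at 13 °C, and 1.34% and 0.396% at 25 °C. Without the 15 such loci on the photosystem list, 25 of 31 members fell, 3 rose and 3 did not pass.

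**Figure D1:**
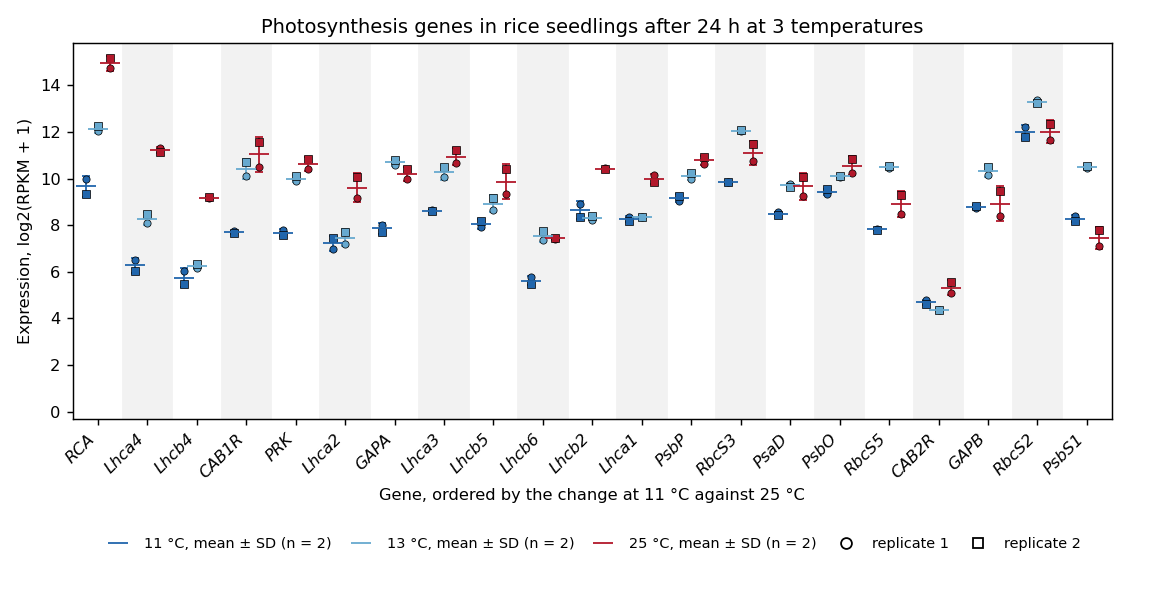
Levels of the photosynthesis genes in each library, as log2(RPKM + 1), with genes ordered along the horizontal axis by their change at 11 °C against 25 °C; dark blue is 11 °C, light blue 13 °C and red 25 °C, circles are replicate 1, squares replicate 2, and dashes with bars are mean ± SD (n = 2). RCA, at the left, lies at 31800 ± 6800 RPKM at 25 °C and 832 ± 258 RPKM at 11 °C.

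Chlorophyll genes split at 11 °C. Of 10 measured synthesis genes, 5 rose, 4 fell and 1 did not pass, the same 5 and 4 adjusted over the list alone. OsPORB, a light-dependent protochlorophyllide oxidoreductase, rose by 2.52 ± 0.3 and the chlorophyll synthase gene YGL1 by 1.84 (adjusted p = 0.00279). OsCRD1, a subunit of the cyclase that closes the isocyclic ring, fell by 2.8 ± 0.26. The median was 0.59, the mean -0.08, and camera pointed down (adjusted p = 0.987). Of 5 chlorophyll breakdown genes, 1 rose, 1 fell and 3 did not pass, counts unchanged adjusted over the list alone (3 and 2 with a replicate block; camera, adjusted p = 0.987). NYC1, a chlorophyll b reductase, rose from 68.5 ± 8.15 to 380 ± 72.9 RPKM and OsPAO, which opens the ring of pheophorbide a, fell by 1.76.

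Most aquaporin genes fell at 11 °C. Of 12 measured list members, 10 fell, 1 rose and 1 did not pass, the same adjusted over the list alone (median -2.59, camera adjusted p = 0.000129; adjusted p = 0.635 with an estimated correlation). The vacuolar channel gene OsTIP1;1 fell 23.1-fold from 205 ± 64.4 to 8.88 ± 0.275 RPKM and OsPIP1;2 by 4.09 ± 0.29. OsPIP2;7 was the member that rose. Among all 24 loci described as aquaporins, 17 fell, 4 rose and 3 did not pass (17 and 5 adjusted over the list alone), with an adjusted p = 0.000435 from camera and an adjusted p = 0.744 with an estimated correlation. TIP4-1 (LOC_Os05g14240) was among the 4 that rose, from 6.84 to 155 ± 18 RPKM (4.32 ± 0.22). The root marker OsLsi1, a silicon channel of the same protein family, fell from 15.5 ± 3.67 to 0.741 RPKM (-3.23 ± 0.26), and was the only root marker measured.

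**Figure D2:**
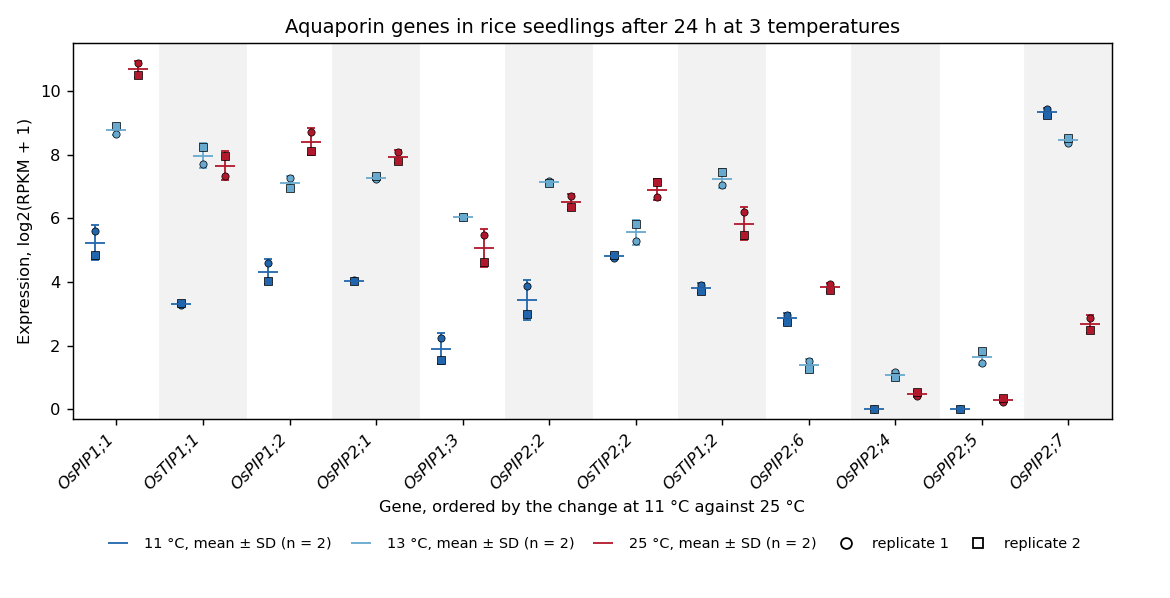
Levels of the aquaporin list members in each library, as log2(RPKM + 1), ordered along the horizontal axis by change at 11 °C against 25 °C; dark blue is 11 °C, light blue 13 °C and red 25 °C, circles are replicate 1, squares replicate 2, and dashes with bars are mean ± SD (n = 2). OsPIP2;7, at the right, rose at both low temperatures, while OsPIP1;1 lies at 37.9 ± 14.2 RPKM at 11 °C and 1650 ± 303 RPKM at 25 °C.

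Among the lists of expansins, cellulose synthases, tubulins and kinesins, and lipid transfer proteins, camera called only the expansins at 11 °C. All 6 expansin genes that changed at 11 °C fell and 3 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.635 with an estimated correlation). They include expansin-A4 (LOC_Os05g39990, -2.51 ± 0.21) and expansin-like A1 (LOC_Os03g04020, -2.29), whose products loosen growing walls. Of 4 cellulose synthase genes, OsCESA1 rose by 1.72 ± 0.26, 2 fell, OsCESA8 by 1.39, and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 0.495). Of 51 tubulin and kinesin genes, 14 rose, 4 fell and 33 did not pass (13 and 3 adjusted over the list alone, 23 and 11 with a replicate block; camera adjusted p = 0.42). Tubulin beta-2 (LOC_Os03g01530) rose by 2.67. Both measured cuticle and wax genes, WSL1 (-1.49) and OsGL1-1 (-1.28), fell, also adjusted over the list alone. Of 28 lipid transfer protein genes, 4 rose, 9 fell and 15 did not pass, the same adjusted over the list alone (8 and 11 with a replicate block; camera adjusted p = 0.301), with LOC_Os05g40010 up by 2.73 and LOC_Os11g02400 down by 2.74.

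In the lists of cold and dehydration factors, WRKY and NAC genes, more members rose than fell at 11 °C. In the list of cold and dehydration factors, 12 of 19 rose, 2 fell and 5 did not pass, the same adjusted over the list alone (median 1.19, camera adjusted p = 0.00863; adjusted p = 0.757 with an estimated correlation). OsWRKY71, a defence regulator that also acts in cold, rose 17.6-fold from 8.7 ± 2.7 to 153 ± 38.7 RPKM. OsMYB4, which raises chilling tolerance when overexpressed, rose by 3.35 ± 0.25. WRKY genes had 29 rises, 8 falls and 22 not passed of 59 (33 and 8 adjusted over the list alone; camera adjusted p = 0.00318; adjusted p = 0.966 with an estimated correlation), led by WRKY33 (LOC_Os01g61080) at 5.26 ± 0.28. NAC genes had 23 rises, 4 falls and 19 not passed of 46, the same adjusted over the list alone; NAC100 (LOC_Os03g21030) rose by 3.16 and NAC21/22 (LOC_Os08g10080), an auxin-pathway factor, fell from 132 to 2.35 RPKM. The NAC list passed camera at an adjusted p = 0.0243 (adjusted p = 0.966 with an estimated correlation) but not without replicate 2 at 25 °C (adjusted p = 0.0567).

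No other regulator family passed camera at 11 °C. AP2/ERF genes had 27 rises, 10 falls and 18 not passed of 55 (28 and 11 adjusted over the list alone; camera adjusted p = 0.0549), with the ERF gene LOC_Os01g21120 up by 6.54 ± 0.28. The AP2/ERF list was called by fry (adjusted p = 0.00927), and by camera under quantile scaling (adjusted p = 0.0349) and without replicate 2 at 11 °C (0.0206), replicate 1 (0.0457) or 2 (0.0455) at 13 °C, or replicate 1 at 25 °C (0.00918). MYB genes had 29 rises, 11 falls and 25 not passed of 65, unchanged adjusted over the list alone (camera adjusted p = 0.382), and the Zm38-type repressor gene LOC_Os08g43550 fell by 4.04. Zinc finger genes had 19 rises, 8 falls and 33 not passed of 60 (17 and 8 adjusted over the list alone, 24 and 16 with a replicate block; camera adjusted p = 0.752); the CCCH gene LOC_Os08g38120 rose by 2.71, and the list median of 0.11 turned to -0.04 under TMM-type scaling. The auxin response list, drawn from words in descriptions, is not limited to regulators. It had 4 rises, 10 falls and 15 not passed of 29, the same adjusted over the list alone (8 and 14 with a replicate block, camera adjusted p = 0.229). Among its members were IAA15 (LOC_Os05g08570) at 1.81 and an enzyme gene, the ILR1-like 5 hydrolase (LOC_Os04g44110), at -2.31.

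Genes of the jasmonate and abscisic acid pathways changed in part. Of 9 jasmonate genes, 6 rose, none fell and 3 did not pass, the same adjusted over the list alone (7 and 1 with a replicate block). OsJAZ12 (4.47 ± 0.24, from 1.55 ± 0.36 to 55.4 ± 5.38 RPKM) and OsJAZ10 (3.7 ± 0.27) encode repressors of jasmonate responses, and OsMYC2 (1.65 ± 0.21) the activator they bind. The list passed camera at an adjusted p = 0.0373 (adjusted p = 0.757 with an estimated correlation), but not with a replicate block (adjusted p = 0.0691), with a pseudocount of 0.1 (adjusted p = 0.0535) or without replicate 1 at 11 °C (adjusted p = 0.0591). Of 10 abscisic acid genes, 3 rose, 3 fell and 4 did not pass, the same adjusted over the list alone (3 and 5 with a replicate block). OsABA8ox1, an abscisic acid hydroxylase, rose from 1.85 ± 0.786 to 70 ± 4.39 RPKM, and the synthesis gene OsNCED3 rose by 1.48. The locus listed as OsNCED1 (LOC_Os02g47510), which the table describes as a carotenoid cleavage dioxygenase 4, fell by 1.34. The median was -0.37, the mean 0.3, and camera pointed down (adjusted p = 0.824).

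Clock genes took opposite directions at 11 °C. OsPRR1, an evening-phase repressor, rose 124-fold from 1.31 ± 0.0664 to 163 ± 31.7 RPKM, OsGI from 14.1 ± 6 to 523 ± 105 RPKM, and OsLUX by 4.39 ± 0.31. The morning gene OsLHY fell 18-fold from 2050 ± 560 to 114 ± 1.75 RPKM. Of 9 clock genes, 5 rose, 2 fell and 2 did not pass (6 and 2 adjusted over the list alone; camera adjusted p = 0.0587; fry adjusted p = 0.00785). Camera called the clock list under quantile scaling (adjusted p = 0.0373) and without replicate 2 at 11 °C (0.0267), replicate 1 (0.0457) or 2 (0.0455) at 13 °C, or replicate 2 at 25 °C (0.0486).

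**Figure D3:**
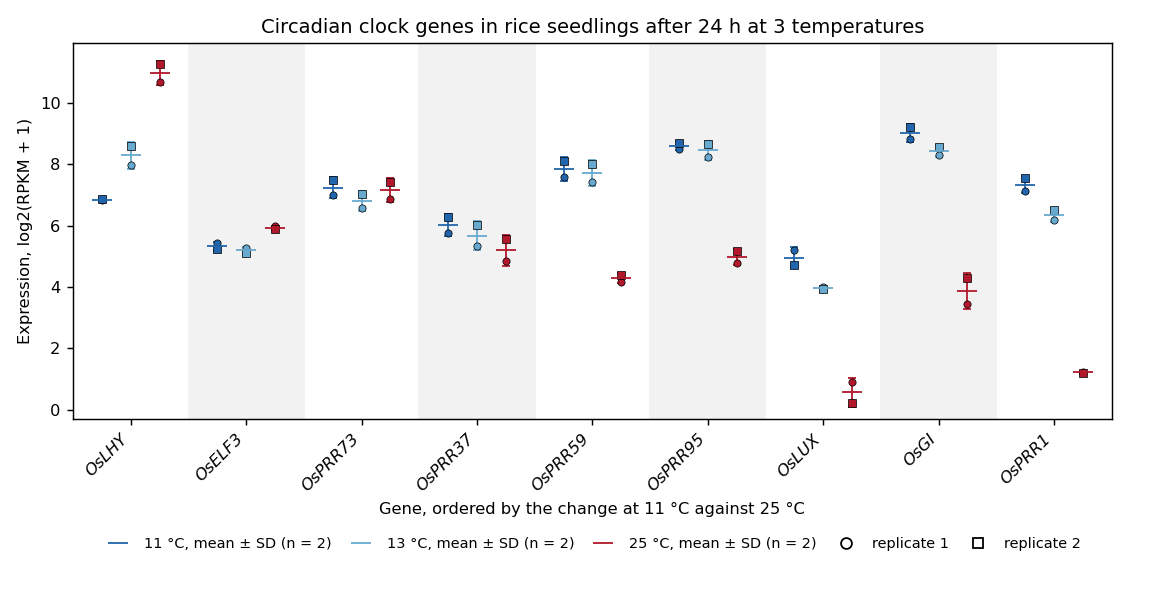
Levels of the clock genes in each library, as log2(RPKM + 1), ordered along the horizontal axis by change at 11 °C against 25 °C; dark blue is 11 °C, light blue 13 °C and red 25 °C, circles are replicate 1, squares replicate 2, and dashes with bars are mean ± SD (n = 2). OsPRR1 lies at 163 ± 31.7, 80.7 ± 12.7 and 1.31 ± 0.0664 RPKM at 11, 13 and 25 °C.

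Ribosomal protein genes were the largest group to rise at 11 °C. Of 319, 178 rose, 17 fell and 124 did not pass (181 and 17 adjusted over the list alone; median 0.83; camera adjusted p = 1.12e-06; adjusted p = 0.635 with an estimated correlation). The plastid-type 30S protein S1 (LOC_Os05g45920) rose from 0.146 ± 0.0143 to 47.7 ± 13.1 RPKM and L12 (LOC_Os05g49320) by 3.8 ± 0.23. Histone genes had 17 rises, 4 falls and 15 not passed of 36, the same adjusted over the list alone, with H2AXb (LOC_Os03g51200) up by 2.88 and H2B.10 (LOC_Os01g05630) by 2.58. Their camera call (adjusted p = 0.0243; adjusted p = 0.757 with an estimated correlation) was absent without replicate 1 at 11 °C (adjusted p = 0.0771) and without replicate 2 at 25 °C (adjusted p = 0.102). Of 47 small heat shock protein and chaperone genes, 13 rose, 20 fell and 14 did not pass (15 and 20 adjusted over the list alone). The mitochondrial HSP70 (LOC_Os09g31486) rose by 4.51 ± 0.23 and chaperonin CPN60-2 (LOC_Os10g32550) by 4.09 ± 0.35. The median was -0.45, the mean 0.1, and camera pointed down (adjusted p = 0.356). In the short list of heat shock proteins and factors, 1 rose, 1 fell and 2 did not pass, also adjusted over the list alone; HSP101 rose by 1.44 ± 0.19, the median was -0.03, the mean 0.16, and camera pointed down (adjusted p = 0.987).

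Receptor-like kinase genes had 109 rises, 34 falls and 102 not passed of 245 (111 and 34 adjusted over the list alone; camera adjusted p = 0.00451; adjusted p = 0.983 with an estimated correlation), among them CRK LOC_Os07g43560 (3.59) and WAK5 (LOC_Os02g56370, 3.24). Cytochrome P450 genes had 42 falls, 18 rises and 34 not passed of 94 (43 and 18 adjusted over the list alone; camera adjusted p = 0.0026; adjusted p = 0.757 with an estimated correlation), with 71A1 (LOC_Os01g12760) at -3.24 and 87A3 (LOC_Os11g18570) at -3.37. Transposable element genes had 29 rises, 5 falls and 32 not passed of 66, the same adjusted over the list alone (37 and 10 with a replicate block), LOC_Os01g68160 rising by 3.89. Their adjusted p = 0.0405 (adjusted p = 0.983 with an estimated correlation) became 0.0778 under quantile scaling, 0.0623 without replicate 1 at 11 °C and 0.0834 without replicate 1 at 25 °C.

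No stress enzyme list passed camera at 11 °C, while fry called the antioxidant list (adjusted p = 0.00825) and the LEA and dehydrin loci (adjusted p = 0.0375). Of 51 glutathione S-transferase genes, 10 rose, 20 fell and 21 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0722); GSTU17 (LOC_Os07g07320) rose by 6.21 ± 0.28 and LOC_Os10g38710 fell by 3.7. Class III peroxidases had 12 rises, 12 falls and 15 not passed of 39 (13 and 14 adjusted over the list alone; camera adjusted p = 0.5), with peroxidase 1 (LOC_Os04g53640) up by 3.27 and peroxidase 17 (LOC_Os09g29490) by 3.26. Of 11 antioxidant genes, 1 rose, 3 fell and 7 did not pass (1 and 2 adjusted over the list alone, 2 and 3 with a replicate block; camera adjusted p = 0.382), and the ascorbate peroxidase gene OsAPX2 fell by 2.2 ± 0.34. Of 8 dehydrin, LEA and osmolyte genes, 2 rose, 1 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.948); OsProDH, which degrades proline, rose by 1.89 ± 0.37 and OsGolS2, for galactinol, by 1.37 ± 0.23, while the median of 0.06 turned to -0.05 under TMM-type scaling. Of 5 LEA and dehydrin loci taken from descriptions, 3 rose, 1 fell and 1 did not pass, the same adjusted over the list alone (camera adjusted p = 0.915). The only measured locus of the terpene synthase list (LOC_Os02g02930) fell by 1.59. Beta-sesquiphellandrene synthase (LOC_Os08g04500), which the words of that list did not match, changed by -5.77. Of 4 reference genes, UBQ5 rose by 1.55 ± 0.27 and 3 did not pass, also adjusted over the list alone (2 and 2 with a replicate block; camera adjusted p = 0.987), and of 2 meristem markers OsCDKB2-1 rose by 2.85 ± 0.29 and the other fell, also adjusted over the list alone.

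In all, 5566 genes rose and 4153 fell at 11 °C against 25 °C (limma, 9719 of 19438), 7163 of them at least 2-fold. The excess of rises is absent under 2 other scalings: 5678 rose and 5562 fell with TMM-type factors, and 5482 and 5695 with quantile scaling. These scalings moved the median change of all genes from 0.125 to -0.003 and -0.029. They centre the changes, so a near-even split under them does not decide whether the excess is real. With organelle-type loci left out and the values rescaled, 5960 rose and 3853 fell. No list of the 34 tested passed camera with an estimated correlation in any comparison, where 2, 1 and 1 had an unadjusted p under 0.05 at 11 against 25, 13 against 25 and 11 against 13 °C and fry called 17, 12 and 11. That correlation was estimated from 6 libraries without a replicate block, so it includes the deviations that replicate numbers share. With it even ribosomal proteins at 13 °C, with 240 of 319 rising, had a camera adjusted p = 0.657. A missing call there says little about a list. With 2 libraries per temperature and 1 cultivar, replicate spread is poorly known.

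At 13 °C against 25 °C, ribosomal protein genes and single genes of thiamine, starch and sucrose synthesis rose, while more photosystem genes fell than rose. Thiamine thiazole synthase 2 (LOC_Os07g34570) rose 1240-fold to 2430 ± 384 RPKM and phosphomethylpyrimidine synthase (LOC_Os03g47610) 754-fold from 0.335 ± 0.0775 to 252 ± 22 RPKM. The starch branching enzyme gene LOC_Os04g33460 rose 127-fold from 2.68 ± 1.27 to 339 ± 101 RPKM. It rose at 11 °C as well, to 60.3 ± 12.2 RPKM. The photosystem II 10 kDa polypeptide gene (LOC_Os07g05360, chromosome 7, 2453960 to 2456611), part of the oxygen-evolving side, fell 887-fold from 1560 ± 164 to 1.76 ± 0.00388 RPKM. This was the largest fall at 13 °C among the genes ranked by the naming rule. RCA fell 7.03-fold to 4530 ± 536 RPKM.

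Further large rises at 13 °C were the EXORDIUM-type gene LOC_Os02g52010 (6.67 ± 0.22, 379-fold, from 0.368 ± 0.0218 to 139 ± 28.3 RPKM), whose family promotes cell expansion under brassinosteroids, and the basic secretory protease gene LOC_Os10g34930 (6.67 ± 0.37). DnaJ B6-A (LOC_Os03g18870) rose by 6.62 ± 0.29, sigC by 6.41 ± 0.31 and thioredoxin-like 3-1 (LOC_Os02g53400) from 0.474 ± 0.148 to 85.8 ± 2.44 RPKM. The beta-amylase gene LOC_Os07g35880, which releases maltose from starch, rose 30.5-fold from 3.41 ± 1.38 to 104 ± 39.6 RPKM, and the sucrose-phosphatase gene LOC_Os01g27880 rose 10.2-fold from 13.4 ± 1.29 to 136 ± 18.9 RPKM. Lichenase-2 fell by 8.31 ± 0.47 to 0.697 ± 0.143 RPKM and thiosulfate sulfurtransferase 18 (LOC_Os12g24020) fell by 7.33 ± 0.4. Peroxidase 15 (LOC_Os10g02040) fell 293-fold from 214 ± 43 to 0.73 ± 0.226 RPKM, and isocitrate lyase (LOC_Os07g34520), of the glyoxylate cycle, by 6.12 ± 0.25.

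Ribosomal protein genes were again the largest group to rise. Of 319, 240 rose, 6 fell and 73 did not pass (246 and 8 adjusted over the list alone, 263 and 15 with a replicate block; median 1.51; camera adjusted p = 8.06e-19; adjusted p = 0.657 with an estimated correlation). L12 (LOC_Os05g49320) rose by 4.23, S1 (LOC_Os05g45920) by 4.98 to 35.8 ± 9.5 RPKM, and the cytosolic 60S protein P2A (LOC_Os02g32760) by 3.35. Tubulin and kinesin genes had 21 rises, no fall and 30 not passed of 51, the same adjusted over the list alone (29 and 3 with a replicate block), tubulin beta-2 rising by 3.77 and tubulin beta-6 (LOC_Os05g34170) by 2.52. The tubulin call (camera adjusted p = 0.0202; adjusted p = 0.982 with an estimated correlation) was absent without replicate 2 at 13 °C (adjusted p = 0.058) and without replicate 1 at 25 °C (adjusted p = 0.0565). Of 4 cellulose synthase genes 3 rose and 1 did not pass (4 and 0 adjusted over the list alone; camera adjusted p = 0.0937), with OsCESA1 at 2.93 and OsCESA6 at 1.2. Of 4 reference genes, UBQ5 (1.98), eEF1A (1.02) and ACT1 (0.89) rose and 1 did not pass, the same adjusted over the list alone (3 and 1 with a replicate block; median 0.95; camera adjusted p = 0.315; fry adjusted p = 0.03). ACT1 was not called without replicate 1 (adjusted p = 0.0662) or 2 (0.0511) at 13 °C.

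Photosynthesis genes had 7 falls, 5 rises and 9 not passed of 21 at 13 °C, the same adjusted over the list alone (8 and 3 with a replicate block; camera adjusted p = 0.0937). Lhca4 fell by 2.94 and Lhcb4 by 2.92 to 75.9 RPKM, while PsbS1, which dissipates excess light energy as heat, rose from 179 ± 59.1 to 1430 ± 68.2 RPKM (3.02 ± 0.28). In the wider photosystem list 15 fell, 4 rose and 27 did not pass of 46, the same adjusted over the list alone (17 and 7 with a replicate block), and CAB7 (LOC_Os09g26810) rose by 3.37. Its median was 0.03 (-0.12 under TMM-type scaling), its mean -0.45, and camera pointed down (adjusted p = 0.037; adjusted p = 0.982 with an estimated correlation). The adjusted p was 0.153 with a replicate block, 0.12 under TMM-type and 0.3 under quantile scaling, 0.325 without replicate 2 at 13 °C and 0.0809 without replicate 1 at 25 °C. Organelle-type loci, at 4.37% and 0.709% of reads in the 13 °C libraries, stand on this list, and without them 15 of 31 members fell, 3 rose and 13 did not pass. With those loci left out and the values rescaled, the list median was -0.87 and camera gave an adjusted p = 0.000498. Of 10 chlorophyll synthesis genes 6 rose, 2 fell and 2 did not pass, the same adjusted over the list alone (camera adjusted p = 0.354), including the magnesium chelatase genes OsChlI (1.89 ± 0.2) and OsChlD (1.84 ± 0.29), OsPORB (2.62) and YGL1 (2.3).

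Aquaporin list members split evenly at 13 °C, 5 up, 5 down and 2 not passed, the same adjusted over the list alone. OsPIP2;7 rose 64-fold to 349 ± 24 RPKM and OsTIP1;2 by 1.41, while OsPIP2;6 fell by 2.44 ± 0.25 and OsPIP1;1 3.76-fold to 440 ± 52.2 RPKM. The median was 0.47, the mean 0.29, and camera pointed down (adjusted p = 0.981). The root marker OsLsi1 stood at 11.4 RPKM, a log2 change of -0.39 (adjusted p = 0.253). Expansin genes had 4 falls, 1 rise and 4 not passed, the same adjusted over the list alone, with expansin-like A1 (LOC_Os03g04020) at -3.41 and expansin-A4 at -3.0. Their adjusted p = 0.0202 from camera (adjusted p = 0.922 with an estimated correlation) was 0.0569 under TMM-type scaling and 0.0531 without replicate 2 at 13 °C. Cytochrome P450 genes had 33 falls, 21 rises and 40 not passed of 94 (34 and 21 adjusted over the list alone), with 71A1 (LOC_Os01g12760) at -3.84 and 734A6 (LOC_Os03g25500), a brassinosteroid hydroxylase type, at 3.49. The P450 call (adjusted p = 0.0364; adjusted p = 0.982 with an estimated correlation) was absent with a replicate block (adjusted p = 0.0762), under TMM-type (0.12) and quantile (0.0518) scaling, and without replicate 2 at 13 °C (0.0793) or replicate 1 at 25 °C (0.0809).

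No list of regulator genes passed camera at 13 °C. Cold and dehydration factors had 5 rises, 2 falls and 12 not passed of 19, the same adjusted over the list alone (8 and 3 with a replicate block; camera adjusted p = 0.695); OsDREB1B rose by 1.69 to 2.8 ± 0.73 RPKM and OsbHLH002, the ICE1-type activator, from 0.107 to 10.1 RPKM, while OsNAC10 fell by 2.26 ± 0.29. NAC45 (LOC_Os10g42130) rose by 5.2, and the MYBAS2 gene (LOC_Os01g74410) fell by 5.14. Of 10 abscisic acid genes 5 rose, none fell and 5 did not pass (5 and 1 adjusted over the list alone, 6 and 2 with a replicate block; camera adjusted p = 0.354), with OsABA8ox1 at 2.84 and OsABA8ox2 at 1.26. Clock genes had 5 rises, 2 falls and 2 not passed, the same adjusted over the list alone (camera adjusted p = 0.17; fry adjusted p = 0.0163): OsPRR1 rose 61.4-fold, OsGI to 347 ± 48.5 RPKM, OsPRR95 by 3.47 and OsPRR59 by 3.43, and OsLHY fell 6.43-fold. Of 11 antioxidant genes 3 rose, 1 fell and 7 did not pass, the same adjusted over the list alone (5 and 2 with a replicate block), with the superoxide dismutase gene SodCp at 1.39 and the catalase gene CatA at -1.62; median 0.01 (-0.19 under TMM-type scaling) and mean 0.1 stood against a camera direction of down (adjusted p = 0.981).

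In all, 5115 genes rose and 3299 fell at 13 °C (limma, 8414), 6199 of them at least 2-fold. The share of rises among called genes was 60.8%, against 50.8% under TMM-type and 49.9% under quantile scaling, and 60.6% without organelle-type loci. TMM-type and quantile scaling moved the median change from 0.124 to -0.031 and -0.034, so their shares do not decide here either. Without replicate 1 at 13 °C 2015 genes fell, without replicate 2 at 13 °C 3318 rose, and with a replicate block 5099 fell.

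Single genes of sugar, starch and nitrogen metabolism stood far apart between 11 and 13 °C. Sucrose-phosphatase (LOC_Os01g27880), the last step of sucrose synthesis, was 62-fold lower at 11 °C (2.2 ± 0.166) than at 13 °C (136 ± 18.9 RPKM), beta-amylase (LOC_Os07g35880) 125-fold lower, and the ADP-glucose pyrophosphorylase large subunit (LOC_Os05g50380), which commits carbon to starch, 37.6-fold lower (4.96 ± 0.695 against 186 ± 79 RPKM). Higher at 11 °C were the auxin-repressed protein gene LOC_Os11g44810 (59-fold, 1120 ± 351 against 19 ± 3.92 RPKM) and glutamate synthase 2 (LOC_Os05g48200), of ammonium assimilation, 43-fold (305 ± 80.2 against 7.11 ± 0.55 RPKM). OsDREB1B was 12.4-fold and OsWRKY71 20.6-fold higher at 11 °C.

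Other large differences include the photosystem II 10 kDa gene (LOC_Os07g05360), 64.7-fold higher at 11 °C, and the universal stress protein gene LOC_Os05g28740, 43.4-fold higher (235 ± 4.51 against 5.41 ± 0.736 RPKM). Sarcosine oxidase (LOC_Os09g32290) was higher by 5.68 ± 0.3, isoflavone 2'-hydroxylase (LOC_Os03g55230) by 5.52 ± 0.24 and the wall-modifying XTH25 (LOC_Os08g14200) by 4.87 ± 0.31. Lower at 11 °C were beta-sesquiphellandrene synthase (LOC_Os08g04500, -6.63 ± 0.25), LOC_Os12g08760 (76.6-fold), the folate-biopterin transporter 9 gene (LOC_Os07g24230, -5.22 ± 0.23), farnesyl pyrophosphate synthase 2 (LOC_Os04g56230, -5.13 ± 0.25) and the sugar exporter gene SWEET15 (LOC_Os02g30910, 0.017 against 34.1 ± 7.61 RPKM). The adjusted p was 4.89e-05 for all of these except XTH25 (8.34e-05).

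Water channel, photosynthesis and cellulose synthase genes were lower at 11 than at 13 °C. Aquaporins had 9 lower, 2 higher and 1 not passed of 12 (10 and 2 adjusted over the list alone; median -3.02; camera adjusted p = 0.000114; adjusted p = 0.74 with an estimated correlation). OsTIP1;1 was 28.6-fold and OsPIP1;1 11.6-fold lower, OsPIP1;3 lower by 4.14 ± 0.34 and OsPIP2;2 by 3.7 ± 0.31. By description, 11 of 24 aquaporins were lower, 5 higher and 8 not passed (12 and 5 adjusted over the list alone; camera adjusted p = 0.0118; adjusted p = 0.74 with an estimated correlation), a call absent under quantile scaling (adjusted p = 0.0573). The root marker OsLsi1 was lower by 2.83 as well. Photosynthesis genes had 14 lower, none higher and 7 not passed of 21, the same adjusted over the list alone (camera adjusted p = 3.85e-05; adjusted p = 0.74 with an estimated correlation), among them RCA (-2.47), GAPA (-2.83 ± 0.28), CAB1R (-2.71) and RbcS5 (-2.67 ± 0.3). All 4 cellulose synthase genes were lower, also adjusted over the list alone (camera adjusted p = 0.00683; adjusted p = 0.74 with an estimated correlation), OsCESA8 by 2.04 ± 0.28, OsCESA3 by 1.66 and OsCESA6 by 1.65. Expansin genes had 1 higher, 2 lower and 6 not passed of 9, the same adjusted over the list alone (3 and 3 with a replicate block; camera adjusted p = 0.779).

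Chlorophyll synthesis genes had 6 lower, none higher and 4 not passed of 10 at 11 against 13 °C, the same adjusted over the list alone (camera adjusted p = 0.00765; adjusted p = 0.74 with an estimated correlation), with OsCRD1 at -1.96 and OsPORA at -1.01. Chlorophyll breakdown genes had 3 higher and 2 not passed of 5 (4 and 0 adjusted over the list alone, 5 and 0 with a replicate block), NYC1 by 1.47. The breakdown call (camera adjusted p = 0.0345; adjusted p = 0.74 with an estimated correlation) was absent without replicate 2 at 11 °C (adjusted p = 0.0564) and without replicate 1 at 13 °C (adjusted p = 0.0545). The wider photosystem list had 16 lower, 2 higher and 28 not passed of 46, the same adjusted over the list alone, PSB27-H1 (LOC_Os03g21560) lower by 2.38. Its adjusted p = 0.0168 (adjusted p = 0.74 with an estimated correlation) was 0.0655 with a replicate block, 0.125 under quantile scaling, 0.287 without replicate 2 at 11 °C and 0.37 without replicate 1 at 13 °C; organelle-type loci held 4.61% and 2.99% of reads at 11 °C and 4.37% and 0.709% at 13 °C. With those loci left out and the values rescaled, 14 photosystem genes were lower, the median was -0.76 and camera gave an adjusted p = 0.00401. Ribosomal protein genes had 137 lower, 4 higher and 178 not passed of 319 (147 and 5 adjusted over the list alone, 214 and 10 with a replicate block; camera adjusted p = 3.57e-10; adjusted p = 0.74 with an estimated correlation), with 60S P2A (LOC_Os02g32760) at -2.3.

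Among cold, WRKY and AP2/ERF factors, more genes were higher than lower at 11 against 13 °C, with a large part not passed. Cold and dehydration factors had 8 higher, 1 lower and 10 not passed of 19, the same adjusted over the list alone (10 and 2 with a replicate block; camera adjusted p = 0.00683; adjusted p = 0.74 with an estimated correlation), with OsMYB4 at 2.84 and the stomatal regulator SNAC1 at 2.31 ± 0.24 (245 ± 21.6 against 48.4 RPKM). WRKY genes had 22 higher, 4 lower and 33 not passed of 59 (23 and 5 adjusted over the list alone; camera adjusted p = 0.000208; adjusted p = 0.74 with an estimated correlation), WRKY33 (LOC_Os01g61080) by 4.08. AP2/ERF genes had 26 higher, 10 lower and 19 not passed of 55 (30 and 10 adjusted over the list alone; camera adjusted p = 0.00347; adjusted p = 0.74 with an estimated correlation), with LOC_Os06g07030 at 3.97 and LOC_Os04g46440 at -3.94 ± 0.24. The NAC list (13 higher, 10 lower and 23 not passed; 13 and 11 adjusted over the list alone), the MYB list (15, 10 and 40; 16 and 11 adjusted over the list alone) and the zinc finger list (13, 9 and 38; 13 and 9 adjusted over the list alone, 21 and 14 with a replicate block) had camera adjusted p-values of 0.248, 0.233 and 0.412. Of 9 jasmonate genes 4 were higher, 1 lower and 4 not passed, the same adjusted over the list alone (5 and 2 with a replicate block), OsJAZ12 by 4.04, OsMYC2 by 1.76 and the synthesis gene OsAOC lower by 1.43. The jasmonate list had an adjusted p = 0.066 from camera, 0.0403 without replicate 2 at 11 °C and 0.0348 without replicate 1 at 13 °C, and an adjusted p = 0.0118 from fry. Lipid transfer protein genes had 12 lower, 2 higher and 14 not passed of 28 (13 and 3 adjusted over the list alone, 16 and 4 with a replicate block; camera adjusted p = 0.0552; fry adjusted p = 0.0118). Camera called this list with a replicate block (adjusted p = 0.0499), without organelle-type loci (0.0417), and without replicate 1 at 11 °C (0.0144), replicate 2 at 13 °C (0.0183), or replicate 1 (0.0346) or 2 (0.0352) at 25 °C.

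Of 6884 genes that differed between 11 and 13 °C (limma), 3351 were higher and 3533 lower at 11 °C, 4749 of them at least 2-fold, and 11351 differed with a replicate block (5570 higher and 5781 lower). The split turned with the libraries: without replicate 1 at 11 °C 2671 were higher and 1988 lower, and without replicate 2 at 11 °C 1795 and 2314 (4109 in all). Without replicate 1 at 13 °C 1817 were higher and 2720 lower (4537 in all), without replicate 2 at 13 °C 2415 and 1834 (4249 in all), and without organelle-type loci 3756 and 3185.

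The responses to 11 and 13 °C overlapped. RCA, Lhca4, Lhcb4 and OsLHY are among 2191 genes lower at both temperatures, and OsPIP2;7, OsPRR1, OsGI, sigC and thiamine thiazole synthase 2 among 3222 higher at both. Of the genes higher at both, 624 rose further at 11 °C, 461 further at 13 °C and 2137 had no difference called. Of those lower at both, 385 fell further at 11 °C, 253 further at 13 °C and 1553 had no difference called. With a replicate block 8424 genes changed the same way at both, 4916 higher and 3508 lower. Under TMM-type scaling 3314 were higher and 3355 lower at both, and under quantile scaling 3048 and 3310. Called lists of these sizes that were independent would share 1465 genes higher and 705 lower. In simulated data with no effect of temperature that shared only the 25 °C libraries, means of 0.09 genes were higher and 0.19 lower at both. Hardly any gene can be called without an effect, so these counts do not measure how much of the response is shared. The simulation leaves out the deviations that libraries of 1 replicate number share. Changes correlated at 0.685 across genes, against 0.498 in the simulation; genes are not independent replicates. The covariance of the changes was 1.11, against a mean of 0.046 and a maximum of 0.052 in the simulation. Random spread of the 25 °C libraries, as simulated, thus gave a small part of the covariance. The 2 libraries at 25 °C cannot be divided between the comparisons, so any other peculiarity of theirs enters both and cannot be separated.

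Opposite changes against 25 °C were called at 327 genes, 196 lower at 11 and higher at 13 °C and 131 the reverse, and all 327 also differed between 11 and 13 °C. Sucrose-phosphatase (LOC_Os01g27880) was 6.1-fold lower at 11 °C and 10.2-fold higher at 13 °C than at 25 °C. The ADP-glucose pyrophosphorylase large subunit (LOC_Os05g50380; -2.15 at 11 °C, 2.76 at 13 °C), the aquaporin gene OsTIP1;2 (-2.03 and 1.41) and the fatty acid hydroxylase gene P450 86B1 (LOC_Os03g04680; -1.72 and 1.66) belong to the same group. Peroxidase 70 (LOC_Os02g14430; 1.41 and -2.06) and the glutathione S-transferase gene GSTU6 (LOC_Os10g38470; 1.42 and -1.57) are among the reverse. Opposite calls numbered 952 with a replicate block, 556 under TMM-type and 593 under quantile scaling, 549 with voom, 208 without the filter, and 159 to 204 without single libraries.

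Genes known from leaf rolling mutants changed in both directions. NAL1, a protease that shapes leaf width and veins, fell at 11 °C from 24 ± 5.16 to 3.66 ± 0.574 RPKM (-2.42, adjusted p = 0.000283). ROC5, a homeodomain factor that restrains bulliform cells, the cells whose loss of turgor folds a rice leaf, rose from 18.8 ± 0.268 to 50.3 ± 12.1 RPKM (1.35, adjusted p = 0.00205). OSHB3, an HD-ZIP III factor of leaf polarity, rose at 13 °C from 1.23 ± 0.755 to 11.4 ± 2.98 RPKM (2.49, adjusted p = 0.000659). SRL2 was lower at 11 than at 13 °C by 1.51 (adjusted p = 0.00615) and NAL1 by 1.42 (adjusted p = 0.00597).

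Other calls in the leaf rolling list were lost in fits without a single library. Such fits have unequal replicate numbers between temperatures and fewer libraries to estimate the spread. A lost call therefore does not show that the change rests on the library left out. At 11 °C against 25 °C, OSHB3 (1.4) was not called without replicate 2 at 11 °C (adjusted p = 0.0568) or replicate 1 at 25 °C (0.0586), OSHB4 (1.38) without replicate 2 at 11 °C (0.0547), ADL1 (1.32) without replicate 2 at 11 °C (0.0827) or replicate 1 at 25 °C (0.0726), and SRL1 (-0.85) without replicate 1 (0.109) or 2 (0.0742) at 11 °C or replicate 2 at 25 °C (0.121). At 13 °C, OSHB4 (1.38) was not called without replicate 2 at 13 °C (0.0619) or replicate 1 at 25 °C (0.0505), SRL2 (1.11) without the same libraries (0.116 and 0.102), ROC5 (0.94) without replicate 2 at 13 °C (0.0828), and NAL1 (-0.99) without replicate 1 at 13 °C (0.144) or replicate 2 at 25 °C (0.118). At 13 °C, too, ACL1 (-0.83) and LC2 (-0.82) were not called without replicate 1 (0.0808 and 0.16) or 2 (0.121 and 0.0508) at 13 °C, nor without replicate 1 (0.0845 and 0.0829) or 2 (0.0683 and 0.0758) at 25 °C. Between 11 and 13 °C, OsZHD1 (-1.29) and CFL1 (-0.95) were not called without replicate 1 at 11 °C (0.104 and 0.159) or replicate 2 at 13 °C (0.0968 and 0.153), and OSHB3 (-1.09) without replicate 1 (0.159) or 2 (0.065) at 11 °C or replicate 2 at 13 °C (0.176), and not with a pseudocount of 0.1 (0.0732). RL14 and OSHB1 passed in no comparison without a block; with a replicate block both passed at 11 °C against 25 °C (adjusted p = 0.0326 and 0.00427).

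Of 13 measured leaf rolling genes, 4 rose, 2 fell and 7 did not pass at 11 °C against 25 °C (4 and 3 adjusted over the list alone, 5 and 8 with a replicate block), 4, 3 and 6 at 13 °C (4 and 3 adjusted over the list alone, 6 and 4 with a replicate block), and none, 5 and 8 between 11 and 13 °C (0 and 5 adjusted over the list alone, 3 and 5 with a replicate block). Camera gave an adjusted p of 0.67, 0.933 and 0.432 in that order, and at 11 °C the median was -0.4 and the mean -0.02. Leaf rolling itself was not analysed here. SLL1, ROC8, NRL1, NAL7, OsAGO7 and REL2 did not pass the expression filter. OsMYB103L and REL1 stand in the table only under upper-case identifiers, which are 0 in every replicate 2 library. Of all upper-case loci, 20 reached an RPKM of 1 in any library. The levels of OsMYB103L and REL1 were not read out here.

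**Figure D4:**
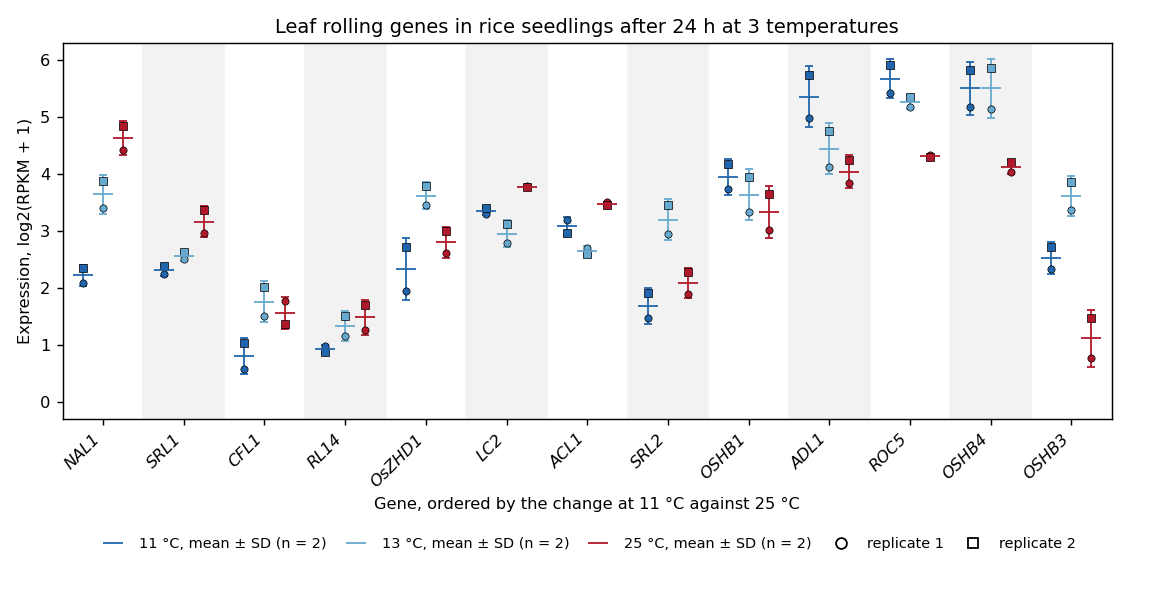
Levels of the measured leaf rolling genes in each library, as log2(RPKM + 1), ordered along the horizontal axis by change at 11 °C against 25 °C; dark blue is 11 °C, light blue 13 °C and red 25 °C, circles are replicate 1, squares replicate 2, and dashes with bars are mean ± SD (n = 2). NAL1, at the left, lies at 3.66 ± 0.574, 11.6 ± 3 and 24 ± 5.16 RPKM at 11, 13 and 25 °C.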

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

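Both tests of the pattern in this part were chosen before their results were seen. Among the 327 genes with opposite changes at 11 and 13 °C, those named by the rule of the methods differ between these temperatures as follows (limma, log2 at 11 against 13 °C, n = 2 per temperature). Lower at 11 °C and higher at 13 °C than at 25 °C were beta-sesquiphellandrene synthase (LOC_Os08g04500, -6.63), LOC_Os06g09600 (-6.09), beta-amylase (LOC_Os07g35880, -5.79), LOC_Os09g26670 (-5.78), sucrose-phosphatase (LOC_Os01g27880, -5.42) and the ADP-glucose pyrophosphorylase large subunit (LOC_Os05g50380, -4.91). The water channel genes OsPIP1;3 (LOC_Os02g57720, -4.14) and OsTIP1;2 (LOC_Os01g74450, -3.44) did the same. So did the cytochrome P450 genes 86B1 (LOC_Os03g04680, -3.38), 78A9 (LOC_Os09g35940, -2.93) and 71D10 (LOC_Os11g41710, -2.69), tubulin beta-6 (LOC_Os05g34170, -3.19), RbcS5 (LOC_Os12g19470, -2.67), OsCESA3 (LOC_Os07g24190, -1.66) and HSP17.4 (LOC_Os03g16020, -1.42).

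Higher at 11 °C and lower at 13 °C than at 25 °C were the following genes. The ethylene response factor genes ERF1B (LOC_Os09g39850) and ERF1 (LOC_Os02g43790) differed by 3.77 and 3.63, and cysteine-rich receptor-like kinases by 3.63 (LOC_Os07g35390), 3.02 (LOC_Os07g35540) and 2.76 (LOC_Os07g35310). Peroxidase 70 (LOC_Os02g14430) differed by 3.46, GSTU6 (LOC_Os10g38470) by 3, MYB108 (LOC_Os11g45740) by 2.64, the CCCH zinc finger gene LOC_Os05g45020 by 2.62, SNAC1 (LOC_Os03g60080) by 2.31 and histone H4 (LOC_Os09g38020) by 1.61. For many of these genes the smaller of the changes against 25 °C is not called when 1 library is left out, for instance SNAC1 at 11 °C without replicate 2 at 11 °C (adjusted p = 0.0966, limma). The exceptions are sucrose-phosphatase, the ADP-glucose pyrophosphorylase gene, OsTIP1;2, P450 86B1 and 78A9, LOC_Os06g09600, peroxidase 70 and GSTU6.

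A mislabelled library could give opposite changes, but the cold replicates correlate with each other better than any cold library does with another temperature, by at least 0.115 across genes (0.972 against 0.857; genes are not independent replicates). Scaling could give them as well, but 299 of the 327 genes keep opposite calls under TMM-type factors. Neither explanation holds for most of these genes. A response that differs in kind between 11 and 13 °C remains possible. With 2 libraries per temperature from 1 series it cannot be told from a difference in collection time or in growth conditions other than temperature.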

How the results depend on the processing

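Tests with voom, without organelle-type loci, and of lists under other scalings or without a library were chosen after seeing the data; count models were planned but not run because the table holds RPKM. Testing only genes with a mean RPKM of at least 5 left 6220 calls of 12224 genes at 11 against 25 °C, 5368 at 13 against 25 °C and 4238 at 11 against 13 °C, and 243 opposite changes, where fewer genes were tested. A replicate block gave 13479, 12228 and 11351 calls, 8424 genes changed the same way in both cold groups and 952 opposite changes; beyond the list calls named in the report and the thiamine lists it changed no other list call. TMM-type scaling gave 11240, 10087 and 8573 calls and 556 opposite changes, and quantile scaling 11177, 9816 and 8770 calls and 593; the cause was not tested. Voom gave 11245, 10083 and 8677 calls and 549 opposite changes. Without the filter there were 9928, 8182 and 6281 calls, with a pseudocount of 0.1 9699, 8310 and 6580, without a trend 9683, 8395 and 6832, with only the 4 libraries of a contrast 9260, 7987 and 7021, and without organelle-type loci 9813, 8390 and 6941. Leaving out single libraries gave 7009 to 9227 calls at 11 against 25 °C, 5949 to 7973 at 13 against 25 °C, and 4109 to 6976 at 11 against 13 °C (4109, 4249 and 4537 in the lowest cases); a group with 1 library left is assumed to vary like the others. Of 30 list calls by camera, 0 remained with an estimated correlation, and 29 with a pseudocount of 0.1; 27 lists were called with a replicate block and 31 without organelle-type loci, in each case with lipid transfer proteins at 11 against 13 °C as a new call (adjusted p = 0.0499 and 0.0417). Fry called the antioxidant list at 13 against 25 °C up (adjusted p = 0.0237), where camera pointed down without a call. Among 10293 values for named genes, 9644 had the same outcome as in the main model, whether called or not called. The call was lost in 423 and gained in 226, and 0 changed direction while called.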

Other observations

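The lists in this paragraph and the next were chosen after seeing the data, and so were the tests of an organelle batch, of collection time and of a graded effect. Of 178 pentatricopeptide repeat genes, whose proteins process organelle RNA, 81 rose, 14 fell and 83 did not pass at 11 °C and 87 rose, 6 fell and 85 did not pass at 13 °C against 25 °C (camera adjusted p = 0.00177 and 4.36e-05; adjusted p = 0.908 and 0.994 with an estimated correlation). Of 55 DEAD-box RNA helicase genes, 27 rose, 4 fell and 24 did not pass at 11 °C and 32 rose, 1 fell and 22 did not pass at 13 °C (with the same adjusted p-values), with RH9 (LOC_Os12g41715) up from 1.29 ± 0.514 to 134 ± 5.99 RPKM at 11 °C and RH3 (LOC_Os03g61220) from 23.1 to 403 ± 42.6 RPKM (n = 2). Aminoacyl-tRNA ligase genes had 19 rises, 1 fall and 34 not passed of 54 at 11 °C (camera adjusted p = 0.00525; adjusted p = 0.908 with an estimated correlation), the glycine ligase gene LOC_Os08g42560 rising by 3.65. Of 7 thiamine genes 4 rose and none fell at 11 °C (camera adjusted p = 0.0256, 0.0592 with a replicate block, and 0.908 with an estimated correlation) and 3 rose and none fell at 13 °C (camera adjusted p = 0.0387, 0.0592 with a replicate block, and 0.994 with an estimated correlation). Thiamine thiazole synthase 2 and phosphomethylpyrimidine synthase, already named for their large rises, are members. The p-values of this list are therefore no independent support for a rise of thiamine genes.

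Between 11 and 13 °C, the list of calmodulins and calcium-binding proteins had 20 higher, 4 lower and 29 not passed of 53 at 11 °C (camera adjusted p = 0.0128, and 0.999 with an estimated correlation). CML36 (LOC_Os12g04360) was higher by 3.38 ± 0.25. The list also holds proteins that bind calmodulin, such as a receptor-like cytoplasmic kinase (LOC_Os03g05470) and a transcription activator (LOC_Os03g27080). U-box and RING ligase genes had 85 higher, 34 lower and 200 not passed of 319 (with the same adjusted p-values), with EL5 (LOC_Os02g35329) at 4.13 and XB3 (LOC_Os03g16780) at 4.57. The list of photorespiration enzymes, drawn from words in descriptions, had 13 lower, 3 higher and 25 not passed of 41 (camera adjusted p = 0.0206, and 0.999 with an estimated correlation). Its words also match phosphoglycerate kinase (LOC_Os05g41640), a phosphoglycerate mutase (LOC_Os01g60190) and D-3-phosphoglycerate dehydrogenase (LOC_Os04g55720). The counts are thus not of photorespiration alone. The glycine cleavage H protein gene LOC_Os10g37180 stood at 50.2, 795 ± 19.3 and 44.1 RPKM at 11, 13 and 25 °C, and starch synthase 1 (LOC_Os06g06560) at 4.7, 127 ± 36.7 and 5.31 RPKM. Of 71 starch and sucrose genes, 19 were higher and 30 lower at 11 than at 13 °C (camera adjusted p = 0.0546). Against 25 °C, 15 rose and 28 fell at 11 °C, and 26 rose and 19 fell at 13 °C. Rises were thus not limited to 13 °C. Isoamylase 1 (LOC_Os08g40930) stood at 65.9 ± 14.1, 23.4 ± 7.19 and 2.4 ± 0.277 RPKM at 11, 13 and 25 °C. Sucrose synthase 4 (LOC_Os03g22120) stood at 101 ± 32.8, 11.3 ± 3.34 and 9.89 ± 2.32 RPKM. Sigma factors had 3 rises and 3 falls of 8 at 11 °C (camera adjusted p = 0.822), and lists of sigma factors, proteasome subunits, DNA replication proteins and sugar transporters were not called in any comparison.

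The 3 replicate 1 libraries differ from the replicate 2 libraries in the same way at every temperature: 600 genes are higher in replicate 1 and 4539 in replicate 2, and the locus LOC_Os01g57968 takes 10.4%, 8.86% and 4.53% of reads in replicate 1 against 2.52%, 0.161% and 0.0471% in replicate 2 at 11, 13 and 25 °C. These counts come from values without further scaling. Loci not of organelle type had a median log2 difference, replicate 1 minus 2, of -0.24, -0.26 and -0.16 at 11, 13 and 25 °C. The counts thus include a shift common to many loci. A library batch with more organelle transcripts in replicate 1 is possible, since the median replicate difference of organelle-type loci exceeds that of other loci by at least 1.54 log2 in each group; the test was set after such loci had been seen to stand apart. Organelle loci are not the whole of it, as without them the replicate deviations still correlate at 0.56 or more between groups, across genes. Gene length bias that differs between the replicate sets does not pass its test, the rank correlation of length with the replicate difference being -0.19 at 11 °C, -0.15 at 13 °C and -0.05 at 25 °C. The changes within the replicate sets correlate at 0.945, 0.941 and 0.952 across genes; genes are not independent replicates.

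The clock genes OsPRR1, OsGI and OsLUX are higher and OsLHY lower at both low temperatures. Scaling of the libraries does not account for this, since the median size of the changes is 3.43 under TMM-type factors and 3.59 without. Collection at another time of day than the 25 °C seedlings could produce it. The test of this asked whether these genes are called in these directions at both low temperatures. That restates the pattern, so it cannot decide. Of the 7 genes called at both, 3 also differ between 11 and 13 °C. This count does not decide either, because collection times are not given in the sources used here. A graded effect of temperature is also possible, as 6 of the 7 genes changed further at 11 °C, but a difference in collection time between the low temperatures would give the same.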
